A study of Mus musculus with 42 samples.

How the data were processed

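The series holds 42 bulk RNA-seq libraries of mouse, per the labels. Of these, 24 come from placental labyrinth, the exchange zone of the mouse placenta, in 4 groups of 6: Trpv2 knockout (KO) and wild type (WT) at embryonic day 14.5 and 16.5 (E14.5 and E16.5). The other 18 come from mouse trophoblast stem cells (mTSC). Scrambled control cells were collected as stem cells (n = 6), after standard differentiation (n = 3) and after differentiation with CHIR99021 (n = 3), an inhibitor of glycogen synthase kinase 3 that activates Wnt signalling. Trpv2 KO cells were collected after standard differentiation (n = 3) and after CHIR99021 (n = 3), and there was no KO stem cell group. Per the labels, tissue RNA went through TriPure extraction and TruSeq stranded mRNA libraries, and cell RNA through RNeasy columns and Illumina stranded mRNA libraries. The labels give no dam, litter, culture or sequencing batch. p-values therefore measure only the spread between these samples, since the labels do not say that they are separate animals or cultures.

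For the labyrinth, the authors deposited RSEM tables of 55416 genes, and the expected counts of these deposited tables were used. For mTSC, the authors deposited Salmon tables of 276707 transcripts with estimated read counts, effective length and TPM, a length-scaled abundance, per the file headers. These estimated counts were summed per gene through the transcript and gene pairs that the labyrinth tables list. This assigned 139675 transcripts to 54137 genes and kept 98.81% to 99.2% of the reads of each library. TPM from the authors' tables served only to weight transcript lengths in 1 alternative, with effective length as deposited. The submitters' processing notes name STAR 2.7.10b, RSEM 1.3.1, Salmon 1.10.3 and the build GRCm39, with no roles. The available annotation, GENCODE M21, is on another build (GRCm38), so only biotype, chromosome and gene order were taken from it and no coordinates are given.

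Total counts per library were 15297986 to 23735119 in labyrinth. In mTSC they were 15909675 to 21643515 in the libraries numbered 47 to 57 (set A: standard differentiation and stem replicates 1 to 3) and 4447101 to 11387283 in those numbered 91 to 128 (set B: CHIR99021 and stem replicates 4 to 6). The median standard error of a log2 fold change was 0.15 for KO against WT at 1 age in labyrinth, between 0.30 and 0.44 across the mTSC comparisons of single conditions or their differences, and 0.22 for KO averaged over both media. No pair of libraries matched closely enough to be a copy (lowest chi-square per gene 8.43).

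Labyrinth and mTSC were fitted separately with edgeR 4.0.16 in R 4.3.3: rounded counts, filterByExpr, TMM normalisation and the robust quasi-likelihood test, with 1 mean per group. This left 16200 genes in labyrinth and 14858 in mTSC. The mTSC design carried a library set term, so standard differentiation was compared with stem replicates 1 to 3 and CHIR99021 with stem replicates 4 to 6. CHIR99021 against standard differentiation is joined only through the stem libraries of both sets. p-values were two-sided and Benjamini-Hochberg (BH) adjusted within a comparison, and a gene was called at an adjusted p under 0.05. Levels are CPM (counts scaled to the TMM-adjusted library size) as mean ± SD and log2 fold changes ± SE. A fold against a group with 0 reads is a bound from a floor of 3 counts over the group, and such bounds cover counting error only.

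For gene lists, 33 lists of 448 genes were tested with camera of limma 3.58.1 (preset correlation 0.01) on voom values, repeated with an estimated correlation, and with fry, with BH adjustment over the lists of a comparison. Beside each call stand the members that passed over all genes and those that passed adjusted over the list alone, and where no count is given beside a call no member passed either way, or 1 count stands for both. The lists covered placental cell types, nutrient transport, calcium and TRP channels, signalling, stress and growth, and 1 listed gene was absent from the tables. Differentiation lists of 100 genes each way were taken from 1 library set and tested in the other, so that list and test shared no library. A library's list score is the mean log2 CPM of the list's genes (prior count 2).

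Named genes followed a rule. Trpv2 came first, then up to 12 genes with the largest log2 fold change each way among called protein-coding genes with a mean of at least 5 CPM and a gene symbol, then up to 4 members of each list by adjusted p, with up to 6 genes each way in the interactions. The comparisons, their tests, the lists, the naming rule and most alternatives were chosen before the data were examined. The KO effect averaged over both ages or both media, the interferon covariate, and leaving out libraries for their Y-linked reads, marker scores or differentiation genes were added after seeing the data. So were the tests of a chromosome segment, of the share of labyrinth cell types, of the spread between cultures and of the gap in depth, and the refits of the share reversed in KO.

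Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter or a stricter filter (mean of 1 CPM), a transcript length offset, fitting only the groups compared, a replicate block, composition scores as covariates, no library set term, and leaving out each library in turn. Whether replicate numbers pair samples was checked as the correlation of same-numbered libraries across genes after removing group means. In standard differentiation against stem this was 0.33 to 0.35, each best with its own number, against a mean of -0.17 with the others. KO against control at each age and in each medium, and the media against each other in scrambled cells, gave no such pairing. KO cells of both media were not compared in this way, and sharing under unequal numbers was not looked for. CHIR99021 against stem was not checked, since its stem replicates carry other numbers. No block was used in the first analysis, so standard differentiation against stem was fitted there without its pairing.

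The pipeline was tested on simulated data with 200 changed genes. In the E14.5 labyrinth design it recovered 62.7% of 1.5-fold, 80.6% of 2-fold and 97% of 4-fold changes. For KO against scrambled cells the 2-fold and 4-fold recovery was 19.4% and 71.2% under standard differentiation, and 28.4% and 66.7% under CHIR99021. False calls numbered 1 to 9 per comparison, and 0 of 20 null lists was called per comparison. Genes were simulated independently of each other and null lists drawn at random, so false calls of lists with correlated genes were not measured. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures. No library was left out of the first analysis, and isoforms were not compared.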

Results

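Gene expression was measured by bulk RNA-seq in 24 labyrinth and 18 mTSC libraries, to ask which genes depend on Trpv2 in the placenta and in trophoblast cells in culture. Libraries held 15297986 to 23735119 counts in labyrinth and 4447101 to 21643515 in mTSC. In a principal component analysis of the labyrinth libraries, the first component (31.5% of the variance) separated E14.5 from E16.5 in all 24 libraries. In mTSC the first component (37.6%) placed the 6 stem libraries between 70 and 95.2. It placed the differentiated libraries between -64.8 and -19.6, except scrambled standard differentiation replicate 3 at 18.7.

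Trpv2, which encodes a calcium-permeable cation channel of the transient receptor potential family (ENSMUSG00000018507, chromosome 11), was examined first, as the targeted gene. In labyrinth at E14.5 it stood at 22.6 ± 2.98 CPM in KO and 180 ± 39 CPM in WT (SD, n = 6 each). This was 7.93-fold lower (log2 fold change -2.99 ± 0.14 SE, edgeR, BH adjusted p = 5.71e-13). At E16.5 it stood at 29.6 ± 4.14 CPM in KO and 159 ± 16.3 CPM in WT, 5.37-fold lower (-2.43 ± 0.13, adjusted p = 3.75e-11). In mTSC the KO level was 3.05 ± 1.82 CPM against 39.7 ± 20.4 CPM in scrambled cells after standard differentiation (n = 3 each, -3.69 ± 0.57, adjusted p = 0.0589). After CHIR99021 it was 3.25 ± 2.3 CPM against 69.1 ± 13.5 CPM (-4.30 ± 0.61, adjusted p = 0.0238). Scrambled stem cells held 10.4 ± 4.77 CPM (n = 6). In scrambled cells Trpv2 rose 4.18-fold with standard differentiation (adjusted p = 0.0143) and 6.12-fold with CHIR99021 (adjusted p = 0.00303). In all 4 contrasts every KO library lay below every control library. The tables do not place the remaining KO reads within the gene.

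**Figure D1:**
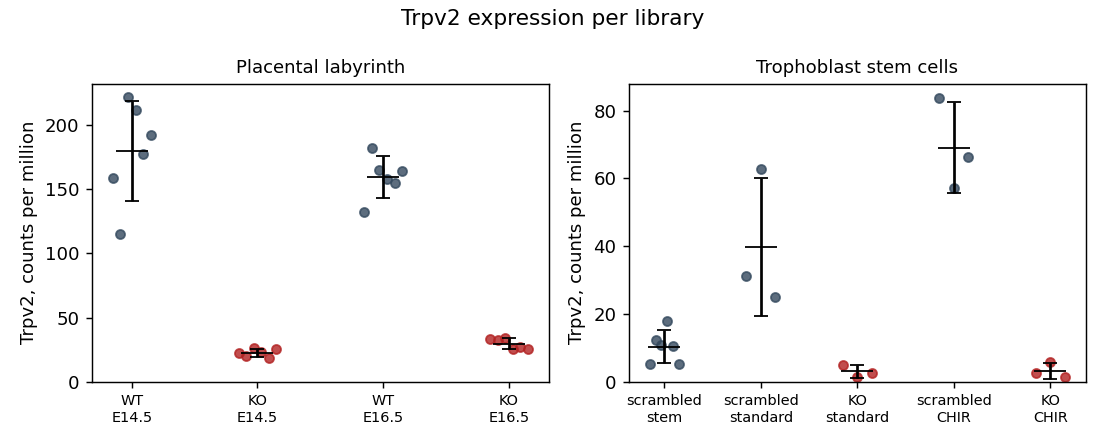
Trpv2 level in CPM in each library (points), by group, with mean ± SD (bars), on separate axes for labyrinth and mTSC. The KO libraries of labyrinth lie between 18.7 and 34.2 and those of mTSC between 1.32 and 5.79, each below every control library of the same age or medium.

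The first comparison asked which labyrinth genes differ without Trpv2 at E14.5. Besides Trpv2, 5 genes fell and 3 rose. Pls3, an actin-bundling plastin, fell from 62.8 ± 5.85 CPM in WT to 46.5 ± 2.75 CPM in KO (SD, n = 6 each, log2 fold change -0.43 ± 0.07, adjusted p = 0.00852). Fhod3, a formin that assembles actin filaments, fell from 38.2 ± 3.72 to 24.4 ± 3.62 CPM (-0.65 ± 0.12, adjusted p = 0.032). Crlf1, a secreted cytokine receptor-like factor, fell 1.99-fold (adjusted p = 0.0125), Zfp354a, a zinc finger gene on chromosome 11, 1.73-fold (adjusted p = 0.0234), and Slc16a10, an aromatic amino acid transporter, 1.29-fold (adjusted p = 0.0457). Parp10, a mono-ADP-ribosyltransferase, rose 1.37-fold from 25.5 ± 1.38 to 34.9 ± 3.86 CPM (adjusted p = 0.0457) and Tor3a, a torsin ATPase, rose 1.72-fold (adjusted p = 0.0426). Hsh2d also rose (1.49 ± 0.29, adjusted p = 0.0457), a gene below the level set for naming and chosen after its values were seen. In all, edgeR called 9 of 16200 genes (3 higher and 6 lower, or 1 and 5 with DESeq2 size factors), with 1455 at an unadjusted p under 0.05 against 810 by chance. Calls numbered 2 without KO replicate 2 or WT replicate 2, 4 or 6, 5 without KO replicate 3 or 6, and 17, 16 and 27 without WT replicate 1, 3 or 5. A fit of these 2 groups alone called Trpv2 alone. The count was 3 with the erythroid score as a covariate, 5 with the junctional zone score, 1 with the interferon score, 15 with the Y-linked score, 19 with the decidua score, 29 with the replicate block and 106 with the DESeq2 Wald test.

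Among the gene lists at E14.5, the markers of syncytiotrophoblast layer II lay lower in KO in 8 of 8 members (median -0.40). This is the inner syncytial layer, which faces the fetal vessels. Synb, the syncytin of that layer, stood at 107 ± 17.7 CPM in KO and 187 ± 41.5 CPM in WT (-0.80 ± 0.18, adjusted p = 0.0848). Gcm1, the transcription factor that starts syncytial differentiation, stood at 24.5 ± 5.01 and 37.3 ± 6.89 CPM (-0.61 ± 0.18, adjusted p = 0.238). None of the 8 passed over all genes and 5 fell when adjusted over the list alone (camera adjusted p = 2.64e-06, and adjusted p = 0.0438 with an estimated correlation). The 12 interferon response genes all lay higher (median 0.32), led by Irf7 (67.3 ± 4.92 against 49.2 ± 8.21 CPM, 0.45 ± 0.10, adjusted p = 0.0775). None passed over all genes and 6 rose when adjusted over the list alone (camera adjusted p = 1.11e-06, and adjusted p = 0.2 with an estimated correlation). 

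Several other lists differed at E14.5 by camera with the preset correlation and lost the call with an estimated one. Fetal endothelium lay lower in 13 of 14 members (median -0.31, adjusted p = 5.65e-06, and adjusted p = 0.31 with an estimated correlation), and Egfl7, an endothelial secreted factor, was the 1 member that passed adjusted over the list alone. The glucose and lactate transport list, which shares Slc16a3 with layer II, had a median of -0.29 with 2 members passing adjusted over the list alone (adjusted p = 0.00195, and adjusted p = 0.2 with an estimated correlation). Parietal trophoblast giant cell markers lay higher in 10 of 10 members (median 0.47, adjusted p = 0.000359, and adjusted p = 0.339 with an estimated correlation) and junctional zone trophoblast markers in 13 of 14 (median 0.39, adjusted p = 0.00164, and adjusted p = 0.504 with an estimated correlation). The list score of the junctional zone spanned 8.56 to 9.5 in KO and 7.79 to 9.25 in WT libraries. Unfolded protein and amino acid response genes had a median of 0.29 and mitochondrially encoded genes of -0.22 (adjusted p = 0.000359 each, and 0.374 and 0.259 with an estimated correlation). Smaller shifts were called for cell cycle (median -0.11, adjusted p = 0.00224), syncytiotrophoblast layer I (-0.22, 0.0158) and angiogenic signals (-0.22, 0.029, with 2 members adjusted over the list alone). The same held for immediate early and heat shock genes (0.13, 0.0393), Wnt beta-catenin targets (-0.16, 0.0393) and erythroid genes (-0.17, 0.0437). All 6 lost the call with an estimated correlation (adjusted p from 0.339 to 0.613). TRP and Piezo channels did not pass as a list (median -0.23, adjusted p = 0.181), and Trpv2 was the 1 member of 22 that passed.

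At E16.5 the same question gave 22 lower and 11 higher genes besides Trpv2. Apela, a peptide hormone ligand of the apelin receptor made by syncytiotrophoblast, fell 2.01-fold from 20.1 ± 4 CPM in WT to 9.99 ± 1.97 CPM in KO (SD, n = 6 each, adjusted p = 0.0082). Slc16a3, a lactate transporter, fell from 211 ± 31.6 to 135 ± 27 CPM (-0.64 ± 0.13, adjusted p = 0.0268) and Slc13a4, a sulfate transporter, from 317 ± 35.5 to 196 ± 40.7 CPM (-0.69 ± 0.14, adjusted p = 0.032). Slc36a1, an amino acid transporter on chromosome 11, fell 2.21-fold (adjusted p = 0.0121) and Kcnj13, a potassium channel, 1.89-fold (adjusted p = 0.00859). Gcgr, the glucagon receptor, fell from 74.7 ± 6.3 to 48.2 ± 8.27 CPM (-0.63 ± 0.13, adjusted p = 0.0329). Gulo fell 1.66-fold (adjusted p = 0.00859), Wfdc2 2.16-fold (adjusted p = 0.0164) and Fhod3 1.61-fold (adjusted p = 0.0101). Tnip1, an inhibitor of NF-kB signalling on chromosome 11, rose from 44 ± 9.49 to 76.8 ± 4.59 CPM (0.80 ± 0.13, adjusted p = 0.0082). Plcg2, a phospholipase, rose 1.55-fold (adjusted p = 0.0146) and Parp10 1.37-fold (adjusted p = 0.0241). With Trpv2, edgeR called 34 of 16200 genes (11 higher, 23 lower), with 1278 at an unadjusted p under 0.05. The count was 14, 22, 19 and 54 without KO replicate 1, 2, 3 or 4, and 19 and 18 without WT replicate 3 or 4. A fit of these 2 groups alone called Trpv2 alone. The count was 11 with the decidua score as a covariate, 20 with the erythroid score, 1 with the interferon score, 55 with the junctional zone score, 53 with the replicate block and 1.1e+02 (to 2 digits) with the DESeq2 Wald test.

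**Figure D2:**
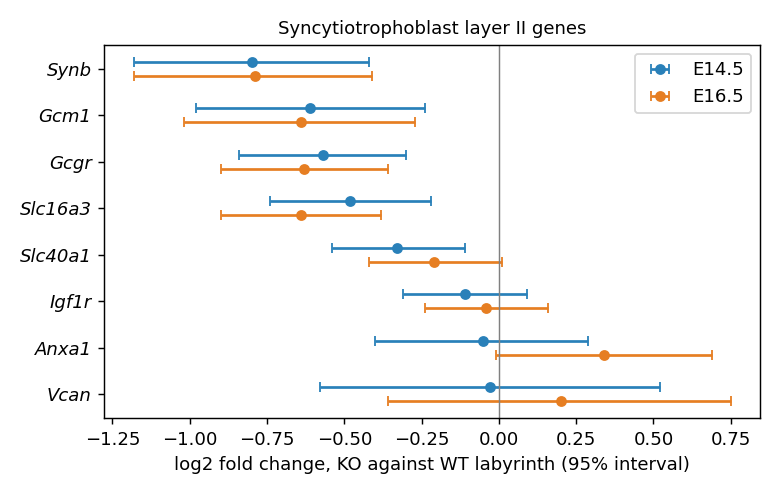
Log2 fold change of KO against WT for the 8 syncytiotrophoblast layer II genes in labyrinth at E14.5 and E16.5, with 95% intervals from the edgeR fit. All 8 values lie below 0 at E14.5, and at E16.5 Anxa1 and Vcan lie above it, with Synb at -0.80 and -0.79.

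Layer II markers again lay lower at E16.5 in 6 of 8 members (median -0.42). The layer II scores of replicates 1 to 3 were 5.89 to 6.12 in KO and 6.46 to 6.58 in WT. In replicates 4 to 6 they overlapped, at 6.28 to 6.38 and 6.37 to 6.58. Y-linked reads numbered at most 10 in replicates 1 to 3, except 1752 in WT replicate 3, and at least 1329 in replicates 4 to 6. This split therefore nearly follows fetal sex as read from Y-linked genes, which the labels do not give. Slc16a3 and Gcgr, both on chromosome 11 as Trpv2 is, fell over all genes, and 4 of 8 fell when adjusted over the list alone. Synb stood at 91.3 ± 31.8 CPM in KO against 158 ± 11.3 CPM in WT (-0.79 ± 0.19, adjusted p = 0.0824). The list passed camera (adjusted p = 4.34e-05, and adjusted p = 0.0538 with an estimated correlation). Glucose and lactate transport genes lay lower in 6 of 6 members (median -0.21), with 1 passing over all genes and 2 adjusted over the list alone, Slc16a3 and the glucose transporter Slc2a3 (camera adjusted p = 4.34e-05, and adjusted p = 0.0538 with an estimated correlation). Interferon response genes lay higher in 12 of 12 members (median 0.33), with none over all genes and 5 adjusted over the list alone (camera adjusted p = 2.38e-09, and adjusted p = 0.0542 with an estimated correlation). Fetal endothelium had a median of -0.20 with 3 members passing adjusted over the list alone (adjusted p = 4.34e-05, and adjusted p = 0.301 with an estimated correlation). Its scores were 4.81 to 5.10 in KO and 5.38 to 5.71 in WT replicates 1 to 3, but 5.14 to 5.62 and 5.02 to 5.75 in replicates 4 to 6. Cell cycle genes lay lower in 17 of 18 members (median -0.27, adjusted p = 0.000108, and 0.533 with an estimated correlation). Erythroid genes had a median of -0.46, with the anion exchanger Slc4a1 passing adjusted over the list alone (adjusted p = 0.00204, and 0.301 with an estimated correlation). Decidua markers, from the maternal side, lay higher in 9 of 10 members (median 0.67, adjusted p = 0.00501, and 0.437 with an estimated correlation). Their scores were 3.75 to 5.01 in KO and 2.48 to 2.72 in WT replicates 1 to 3. In replicates 4 to 6 KO was not higher, at 3.14 to 3.66. There WT stood at 3.32 in replicate 4 and at 3.85 or above in replicates 5 and 6. Calls lost with an estimated correlation were also made for mitochondrially encoded genes (median -0.17, adjusted p = 0.00208, then 0.301) and amino acid transport (-0.15, 0.00683, then 0.301, with 1 member adjusted over the list alone). The same was true of calcium transport and store genes (-0.13, 0.0288, then 0.35, with 1 member adjusted over the list alone) and cholesterol synthesis (0.17, 0.0345, then 0.569). In replicates 1 to 3 calcium scores were 4.03 to 4.19 in KO and 4.34 to 4.66 in WT, and amino acid transport scores 6.50 to 6.61 and 6.82 to 7.04. In replicates 4 to 6 both overlapped, at 4.29 to 4.44 and 4.09 to 4.52, and at 6.67 to 6.85 and 6.56 to 6.98.

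Whether the effect of the KO differs between the ages was tested as an interaction in labyrinth. Synb was lower by nearly the same amount at both ages (-0.80 and -0.79), and the interferon medians were 0.32 and 0.33. Of the 8 genes called at E14.5 besides Trpv2, 8 had the same sign at E16.5, as had 32 of the 33 called at E16.5 when read at E14.5. Among genes at an unadjusted p under 0.05 at both ages, 99 were higher and 264 lower at both against 23.8 and 33.9 by chance, and 12 moved in opposite directions. edgeR called 0 genes for the difference (416 at an unadjusted p under 0.05 against 810 by chance), the DESeq2 Wald test called 1, and no list passed. On simulated data this design recovered 62.7% of 2-fold differences.

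In WT labyrinth, development from E14.5 to E16.5 gave the scale for the KO effect. The embryonic globin Hbb-y fell from 554 ± 183 to 7.15 ± 3.31 CPM (SD, n = 6 each, -6.28 ± 0.46, adjusted p = 2.72e-09), and the adult globin Hbb-bs rose (1.25 ± 0.25). Hsd11b2, which inactivates glucocorticoids, fell from 90.2 ± 24.5 to 4.07 ± 0.83 CPM (adjusted p = 6.46e-10). Doxl2 rose 83.9-fold (adjusted p = 1.07e-08) and Prl3a1, a placental prolactin, rose from 31 ± 12.6 to 450 ± 133 CPM (adjusted p = 2.32e-07). Cell cycle genes fell in 17 of 18 members (median -1.18), among them Mki67 (-2.03 ± 0.26) and Ccna2 (-1.78 ± 0.18), with camera adjusted p = 2.88e-13 and adjusted p = 0.486 with an estimated correlation. Of 16 cholesterol synthesis genes 10 fell and 1 rose, or 13 and 1 adjusted over the list alone (median -0.52), among them Ldlr, the LDL receptor, at -1.23 ± 0.10 (adjusted p = 0.000245 for the list, and 0.575 with an estimated correlation). Sinusoidal trophoblast giant cell markers rose in 6 of 8 members and fell in 1 (median 1.08), with the cathepsin Ctsq at 1.67 ± 0.20 (adjusted p = 0.00135, and 0.223 with an estimated correlation). In the junctional zone list 8 rose and 3 fell of 14, or 9 and 3 adjusted over the list alone (median 0.73, adjusted p = 0.0368, and 0.607 with an estimated correlation), and in the layer I list 5 of 8 fell (median -0.31, 0.0218, and 0.575 with an estimated correlation). Unfolded protein response genes rose in 8 of 11 members, 9 adjusted over the list alone (median 0.58, adjusted p = 0.0107) and macrophage and leukocyte genes in 7 of 13 (median 0.70, adjusted p = 0.0171), both with adjusted p = 0.575 with an estimated correlation. Lists that did not pass were natural killer and T cell genes (median -2.08, adjusted p = 0.0859, 2 members measured), pericyte and stroma (-0.53, 0.0859), mesenchymal and matrix (-0.30, 0.0742) and YAP TEAD targets (0.30, 0.0742). In all, edgeR called 2693 higher and 2611 lower genes (32.7%), of which 603 and 642 changed more than 2-fold.

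In scrambled mTSC, standard differentiation was compared with the stem state. Stem cell genes fell in 15 of 17 members (median -3.83). Sox2, a stem cell transcription factor, went from 125 ± 29.2 CPM in stem cells (n = 6) to 1.2 ± 1.79 CPM (n = 3, adjusted p = 0.00055), Spry4, a feedback inhibitor of FGF signalling, fell 79.8-fold (adjusted p = 2.07e-05) and Cdx2 fell by 2.41 on the log2 scale. The list passed camera (adjusted p = 2.43e-11, and adjusted p = 0.0644 with an estimated correlation). Layer I markers rose in 6 of 8 members (median 3.04, adjusted p = 0.0332, and adjusted p = 0.78 with an estimated correlation), with the syncytin Syna at 5.78 ± 1.35 (adjusted p = 0.009). Their list score was 5.37 and 5.61 in 2 of the differentiated libraries and 2.63 in replicate 3. Of the layer II markers 3 of 8 rose, with Gcm1 at 3.01 ± 0.98 (adjusted p = 0.0419), and the list did not pass (median 1.47, adjusted p = 0.255). Cell cycle genes fell in 11 of 18 members over all genes and 15 adjusted over the list alone (median -0.61, adjusted p = 4.53e-06, and 0.308 with an estimated correlation). Mitochondrially encoded genes rose in 8 of 12 members (median 1.17, adjusted p = 3.98e-05, and 0.344 with an estimated correlation). Lipid transport genes rose in 5 of 12 over all genes and 6 adjusted over the list alone (median 1.04, adjusted p = 0.0127, and 0.308 with an estimated correlation), and 4 of 8 endothelium list genes fell, 5 adjusted over the list alone (median -1.42, 0.0303, and 0.212 with an estimated correlation). edgeR called 1486 higher and 1320 lower of 14858 genes (2937 in all with the replicate block on stem replicates 1 to 3 alone). The total was 1349 without replicate 2 of the differentiated cells, 1422 without stem replicate 1, 1798 in a fit of these groups alone and 4254 without the library set term.

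CHIR99021 differentiation was compared with the stem state in the same way. Stem levels are again means over 6 libraries. Stem cell genes fell in 14 of 17 members (median -2.44, adjusted p = 8.69e-07, and 0.14 with an estimated correlation), with Sox2 at 1.16 ± 1.01 CPM (n = 3, adjusted p = 0.000695). Both syncytial layers rose, layer I in 7 of 8 members, 8 adjusted over the list alone (median 3.04, adjusted p = 0.00531, and 0.44 with an estimated correlation) and layer II in 5 of 8 (median 1.96, adjusted p = 0.0125, and 0.309 with an estimated correlation). Gcm1 rose from 2.62 ± 2.76 to 74.2 ± 30.7 CPM (adjusted p = 0.00509) and Gjb2, the connexin that joins the syncytial layers in the mouse, from 5.17 ± 4.56 to 1100 ± 372 CPM (adjusted p = 0.00112). The sulfate transporter Slc13a4 rose 163-fold (adjusted p = 0.00137), while Hand1, a giant cell transcription factor, fell 6.09-fold (adjusted p = 3.93e-05) and Mmp9, a matrix protease, 72.8-fold (adjusted p = 0.00236). Of 15 Wnt targets 7 rose, among them Znrf3 (2.03 ± 0.22) and the receptor Lgr5 (0.124 ± 0.134 to 15.3 ± 4.26 CPM), and 3 fell, among them T, with 0 reads after CHIR99021 and at least 17.3-fold lower than in stem replicates 4 to 6. The list as a whole did not pass (median 1.65, also with T at its bound, adjusted p = 0.0926). Interferon response genes rose in 9 of 10 members, 10 adjusted over the list alone (median 3.94, or 3.73 with Ifit2 at its bound, adjusted p = 9.14e-06, and 0.219 with an estimated correlation), with Stat1 going from 10.7 ± 3.35 to 121 ± 70.2 CPM. Imprinted growth genes rose in 10 of 15 and fell in 1, or 10 and 2 adjusted over the list alone (median 1.18, adjusted p = 0.00632, and 0.183 with an estimated correlation), led by Peg10 (2.90 ± 0.52) and H19 (2.71 ± 0.57). Epithelial adhesion genes rose in 4 of 14, 5 adjusted over the list alone (median 0.65, adjusted p = 0.00227, and 0.309 with an estimated correlation), and lipid transport genes in 6 of 12, 9 adjusted over the list alone (median 1.39, 0.00227, and 0.183 with an estimated correlation). Cell cycle genes fell in 10 of 18, 12 adjusted over the list alone (median -0.62, 4.82e-05, and 0.219 with an estimated correlation) and endothelium list genes in 5 of 8 (median -2.45, 0.0086, and 0.14 with an estimated correlation). edgeR called 2103 higher and 2205 lower genes (29%). Of the genes called in both differentiations, 894 rose and 873 fell in both against 210 and 196 by chance, and 9 moved in opposite directions. The stem libraries behind each comparison were different ones.

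CHIR99021 and standard differentiation of scrambled cells were then compared with each other through the stem libraries. Interferon response genes had a median of 1.90 (adjusted p = 0.00229), hypoxia response genes of 1.06 (0.00229), mitochondrially encoded genes of -1.33 (4.71e-08) and YAP TEAD targets of -1.15 (0.00257). Unfolded protein response genes stood at 0.67, p53 targets at -0.57 and mesenchymal and matrix genes at -1.11 (adjusted p = 0.0195 each). With an estimated correlation all 7 lists had adjusted p = 0.557. Adjusted over the list alone, 7 mitochondrially encoded genes, 2 YAP TEAD targets and 2 mesenchymal and matrix genes passed. edgeR called 0 genes over all (1903 at an unadjusted p under 0.05 against 743 by chance), and the DESeq2 Wald test 230. The media lie in different library sets, and without the set term 351 genes were called.

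In mTSC after standard differentiation, KO cells were compared with scrambled cells (n = 3 each). Cldn7, a tight junction claudin on chromosome 11, stood at 0.696 ± 0.505 CPM in KO and 26.9 ± 14.9 CPM in scrambled cells (-5.25 ± 0.78, adjusted p = 0.0589), and F3, tissue factor, at -1.20 ± 0.19 (adjusted p = 0.0589). Hand1 stood at 563 ± 31 and 267 ± 33.4 CPM (1.08 ± 0.26, adjusted p = 0.791). All 18 cell cycle genes lay higher in KO (median 0.32, camera adjusted p = 6.4e-07, and adjusted p = 0.311 with an estimated correlation) and all 10 interferon response genes lower (median -2.03, adjusted p = 0.000704, and 0.506 with an estimated correlation). The interferon scores of the libraries overlapped, at 1.96, 3.32 and 0.96 in scrambled and 0.55, 0.91 and 1.27 in KO replicates 1, 2 and 3. Smaller list calls, each lost with an estimated correlation (adjusted p from 0.311 to 0.831), were hypoxia response (0.32, adjusted p = 0.0306), labyrinth trophoblast progenitor (0.35, 0.0356), mitochondrially encoded (-0.31, 0.0397) and sex-linked genes (-0.36, 0.0283). No member of these 6 lists passed over all genes. KO replicate 1 held 0 Y-linked reads, and leaving out the KO libraries without them turned the sex-linked median to 0.23. edgeR called 0 of 14858 genes (589 at an unadjusted p under 0.05 against 743 by chance), the DESeq2 Wald test 19, and on simulated data this design recovered 71.2% of 4-fold changes.

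After CHIR99021 the interferon response genes stood far lower in KO than in scrambled cells. All 10 measured members were lower (median -3.12), Stat1 at 30.5 ± 6.1 against 121 ± 70.2 CPM (-1.99 ± 0.47, adjusted p = 0.335), Irf7 at 1.71 ± 0.972 against 16.7 ± 3.36 CPM (-3.21 ± 0.71, adjusted p = 0.307), and Ifit2 at 0 against 33 reads, at least 14.8-fold lower. None passed over all genes and 10 fell when adjusted over the list alone (camera adjusted p = 1.1e-18, adjusted p = 0.0498 with an estimated correlation, median also -3.12 with Ifit2 at its bound). All 18 cell cycle genes lay higher (median 0.42, adjusted p = 1.61e-11, and 0.08 with an estimated correlation). Layer II markers lay lower in 7 of 8 members (median -1.08, adjusted p = 0.00189, and 0.259 with an estimated correlation) and stem cell genes higher in 17 of 17 (median 0.46, adjusted p = 0.0209, and 0.539 with an estimated correlation). Lipid transport genes had a median of -0.39 with 1 member passing adjusted over the list alone (adjusted p = 0.00113, and 0.205 with an estimated correlation) and Wnt targets of 0.22, or 0.20 with T at its bound (adjusted p = 0.645). In KO replicate 3 the layer I score was 2.65 against 5.46 and 6.13 in the other two. Cldn7 again stood lower (2.76 ± 2.52 against 46.9 ± 8.63 CPM, adjusted p = 0.233). Over all genes edgeR called 2, Trpv2 and Gm20683, with 1015 at an unadjusted p under 0.05. Gm20683, named after its values were seen, had 57 reads in KO and 0 in scrambled cells, at least 14.1-fold higher. Calls numbered 0 without any 1 of the scrambled replicates, without KO replicate 1 or 3, with the replicate block and in a fit of these groups alone. They numbered 3 without KO replicate 2, and 44 with the DESeq2 Wald test.

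**Figure D3:**
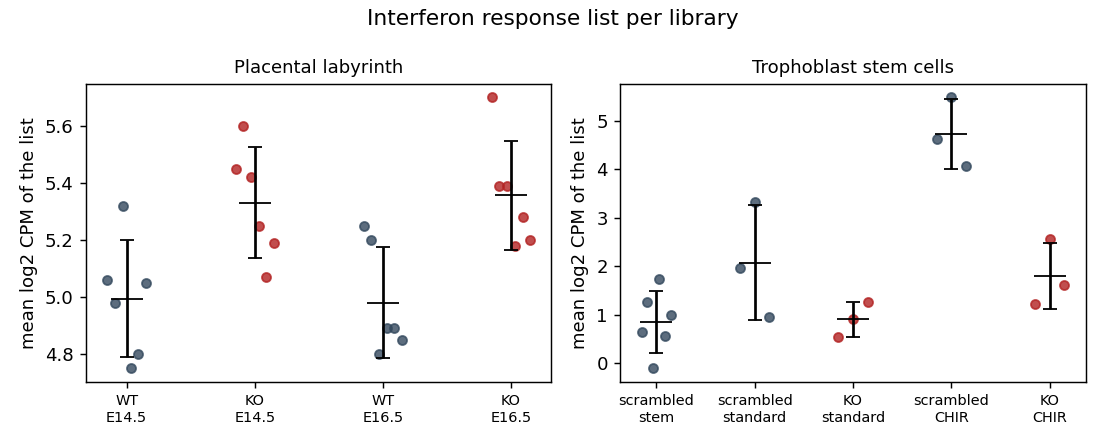
Interferon response score (mean log2 CPM of the list) of each library (points), by group, with mean ± SD (bars), on separate axes that do not start at 0. After CHIR99021 the 3 scrambled libraries lie at 4.07 to 5.49 and the 3 KO libraries at 1.23 to 2.56. Over all replicates KO and WT labyrinth overlap, at 5.07 to 5.70 and 4.75 to 5.32. Split by replicate number after the values were seen, every KO library lies above every WT library of its age. The lowest KO and highest WT scores at E14.5 are 5.42 and 5.32 in replicates 1 to 3, and 5.07 and 5.05 in replicates 4 to 6. At E16.5 they are 5.39 and 5.25, and 5.18 and 4.89. Y-linked reads are few in replicates 1 to 3 and many in 4 to 6, except many in WT replicate 3 at E16.5.

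Whether the KO effect differs between the media was tested as an interaction. The interferon response genes differed most, with a median difference, CHIR99021 minus standard, of -1.31 (camera adjusted p = 4.03e-05, and adjusted p = 0.42 with an estimated correlation). Mitochondrially encoded genes had a median of 0.60 (0.000193, then 0.42), and stem cell genes of 1.08 (0.0199, then 0.567). edgeR called 0 genes (283 at an unadjusted p under 0.05 against 743 by chance) and the DESeq2 Wald test 4. On simulated data this design recovered 40.9% of 4-fold differences.

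The genes of differentiation were carried across the library sets to ask whether KO cells differentiate as far. The 100 genes that rose most surely in standard differentiation lay lower in KO after CHIR99021 in 80 of 100 cases (median -0.22, camera adjusted p = 1.3e-09, adjusted p = 0.0471 with an estimated correlation, and 0.0545 with 200 genes), and the 100 that fell lay higher (median 0.22, adjusted p = 0.00494, and 0.194 with an estimated correlation). KO CHIR99021 replicate 3 stood apart (-19.6 on the first principal component, against -57.4 and -52.1 in the other two and -48.9 to -64.8 in scrambled cells). Without it the median of the rising genes was -0.43 (adjusted p = 2.27e-12, and 0.031 with an estimated correlation), and the falling genes lost the call (0.15, adjusted p = 0.109). Without any 1 of the other 5 libraries the rising genes lost the call with an estimated correlation (adjusted p from 0.0635 to 0.146). Genes taken from CHIR99021 and tested in KO after standard differentiation gave no call. Those that rise had a median of -0.17 with a camera direction upward, so the signs differ (adjusted p = 0.594), and those that fall had -0.19 (adjusted p = 0.152). The median of the rising genes was -0.56 without scrambled standard replicate 3 and 0.32 without replicate 2, so these medians rest on single libraries.

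**Figure D4:**
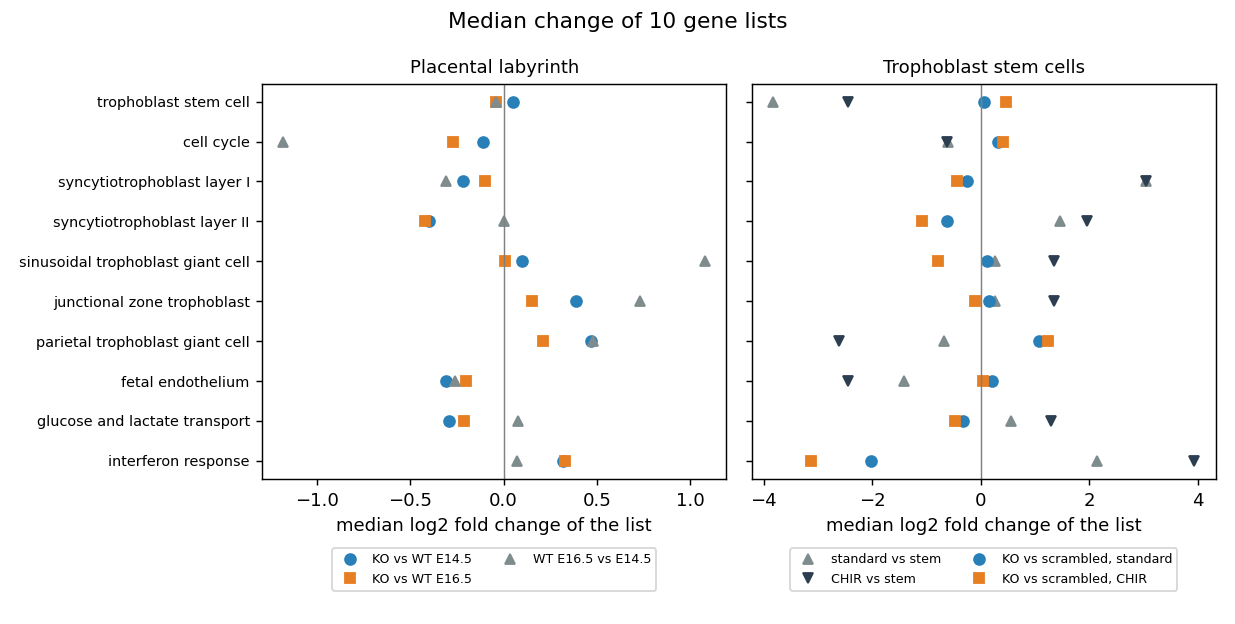
Median log2 fold change of 10 gene lists for KO against control (circles and squares) and for development or differentiation in control samples (triangles), in labyrinth on the left and mTSC on the right, with a wider axis for mTSC. For KO against control the interferon list stands at 0.32 and 0.33 in labyrinth and at -2.03 and -3.12 in mTSC.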

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

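The tests of a chromosome segment, of a lower share of all labyrinth cell types, of the spread between cultures and of the gap in depth were chosen only after their results had been seen, as were the values for genes near Trpv2 alone and the refits of the share reversed in KO. Each pattern below was found and tested on the same data, so what is offered is a hypothesis.

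Of the 37 genes called in KO labyrinth at either age besides Trpv2, 7 (Zfp354a, Kif3a, Slc36a1, Tnip1, 9530068E07Rik, Sarm1 and 9930111J21Rik2) lie within 300 tested genes of Trpv2 on chromosome 11. This is an odds ratio of 6.11 against all other tested genes (95% interval 2.26 to 14.3, Fisher's exact p = 0.000366), and 2.96 (1.86 to 4.53) for the genes called over both ages, so a chromosome segment inherited with the knockout allele may account for part of the calls. The window holds 600 of the 1275 tested genes of chromosome 11 besides Trpv2, and Tom1l1, Gcgr and Slc16a3 were called outside it. Closeness to Trpv2 was therefore not set apart from lying anywhere on that chromosome. A differing junctional zone share of the dissections is argued against, since a junctional zone covariate left 0.94 of the median absolute log2 fold change of all 10 called genes on chromosome 11 (0.58 before and 0.54 after) and 0.89 of that of the 7 (0.66 and 0.59). Loss of TRPV2 itself stays open, because in KO mTSC the 9 measured of these 10 moved by a mean of 0.18 in the labyrinth direction with an interval of -0.12 to 0.60, against 0.56 in labyrinth, and 5 shared the sign. For the 6 measured of the 7 near Trpv2 the mean was -0.02 (-0.19 to 0.18) against 0.58 in labyrinth, so no such shift was seen in mTSC. Both mTSC intervals come from resampling the genes, not the libraries, and leave out the spread between libraries. They therefore do not decide against loss of TRPV2 itself, and mTSC may not stand for labyrinth.

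The syncytiotrophoblast layer II list had a mean of -0.34 in KO labyrinth over both ages, with 0 of 8 members passing over all genes at E14.5 and 2 of 8 at E16.5, where Vcan (0.20) and Anxa1 (0.34) lay higher and the list lost its call with an estimated correlation (adjusted p = 0.0538). More junctional zone tissue in the KO dissections is argued against as the whole cause, since 0.85 of the mean was left with that covariate (-0.28) and the list still passed fry of limma. Y-linked signal was nearly even between KO and WT, save for an extra WT library with many such reads at E16.5. This leaves little room for unequal Y-linked signal as a cause. For the same reason a Y-linked covariate had little to remove. That 0.99 of the mean was left with it (-0.33), the list again past fry, therefore adds nothing. The covariate also does not test for a KO effect confined to fetuses of a single sex. A lower share of all labyrinth cell types stays open, since layer II scores fell short of the mean of layer I and endothelium by a KO minus WT difference of -0.13 with a permutation p of 0.0551. The 2 members that passed at E16.5, Slc16a3 and Gcgr, lie on chromosome 11 with Trpv2, farther than 300 tested genes from it. Whether alleles inherited with the knockout account for their fall was not tested. An effect of genotype on layer II, which the design names, remains a candidate explanation beside these.

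The interferon response score in KO mTSC differed by -2.05 over both media, with no member passing over all genes, the call lost with an estimated correlation (adjusted p = 0.0659, and 0.506 after standard differentiation) and scores that overlap after standard differentiation (0.96 to 3.32 in scrambled and 0.55 to 1.27 in KO). Spread between cultures regardless of genotype stays open. The exact permutation p was 0.01 over the 400 relabellings of KO and scrambled within the media. These relabellings take the libraries of both media as separate cultures, which the labels do not state. A KO library of each medium held 0 Y-linked reads, so the same KO lines may have served both media. The permutation p would then be too small. Less advanced differentiation of the KO cultures stays open, since the share of the CHIR99021 change that KO reversed was 0.21 times as large for the 100 rising genes as for interferon genes (95% interval 0.13 to 0.35), but 0.40 times (0.25 to 0.73) without KO CHIR99021 replicate 3. These intervals come from resampling genes and leave out the spread between libraries. Lower depth is argued against, not by the planned thinning of the CHIR99021 libraries to 4411480 counts (median -3.12 before and after), which had no lower KO depth to remove (lowest KO total 4555569), but as the deepest scrambled library exceeded the shallowest KO library by 0.33 on the log2 scale at most (0.21 after CHIR99021), against a quartile of the list nearest 0 of -1.38 after standard differentiation and -2.60 after CHIR99021. An effect of genotype may underlie it, but a difference between KO and scrambled lines stays open and untested, since the labels name no clones and 2 KO libraries held 0 Y-linked reads against 542 or more in the other 4 (median -2.61 over both media without these 2, against -2.49).

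Groups of 4 to 10 libraries were searched for a library far from the others in depth, Trpv2 or list scores, over 174 sets of values. Chance marks about 1 in 20 such sets, and 9 were found. In WT at E14.5 the parietal giant cell score was 4.47 in replicate 4 (others 5.41 to 5.87), the mesenchymal score 5.94 in replicate 3 (6.19 to 6.31), the immediate early score 3.79 in replicate 6 (4.12 to 4.26) and the mitochondrial score 7.65 in replicate 2 (8.37 to 8.53). In KO at E16.5 the junctional zone score was 10.13 in replicate 2 (9.32 to 9.57) and the cell cycle score 2.74 in replicate 1 (3.17 to 3.37). In WT at E16.5 the macrophage score was 4.29 in replicate 2 (3.32 to 3.63) and the cholesterol score 4.34 in replicate 1 (4.57 to 4.69). In stem cells the angiogenic score was 3.47 in replicate 3 (2.71 to 2.96).

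The KO effect differed between media for 7 lists in the camera test of the interaction, CHIR99021 minus standard, each lost with an estimated correlation. The medians were -1.31 for interferon response, 0.60 for mitochondrially encoded genes, -0.31 for cholesterol synthesis, -0.27 for lipid transport, 0.30 for unfolded protein response, 1.08 for stem cell genes and -0.41 for layer II. The KO effect also differed between labyrinth and mTSC. The interferon score difference was 0.36 in labyrinth and -2.05 in mTSC, a gap of 2.41 (permutation p = 5e-05), and the cell cycle gap was -0.58 (permutation p = 0.00023), while the layer II gap of 0.30 did not pass (permutation p = 0.502). These permutations treat the mTSC libraries of both media as separate cultures, which the labels do not state.

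Other splits of the same libraries were fitted the same way. By the adjusted count chance was argued against at E14.5. There 1 of 100 splits gave as many as the real 9 genes, and the highest other gave 4. Without Trpv2, whose fall the design fixes, the real count of 8 stood against 4. At an unadjusted p under 0.05, 6 of 100 splits gave as many, so chance was not excluded. For WT age it was excluded, with 1 of 100 (5304, highest other 1483). For the KO effect averaged over both ages 1 of 100 splits reached the real count (252 against 158), as did 1 of 100 over both media (5 against 4). When Trpv2 is not counted, 3 of 100 reached the count over both media, with 4 against 4. At an unadjusted p under 0.05, 11 and 10 of 100 splits gave as many genes, so chance was not excluded for either. At E16.5, 4 of 100 splits reached the adjusted count of 34, and 20 of 100 gave as many genes at an unadjusted p under 0.05, so chance was not excluded. The 3 others that reached 34 gave 4871, 4076 and 202, which points to a structure of the samples. Whether these splits follow the replicate numbers, and with them the Y-linked reads, was not examined. KO layer II scores were 5.89 to 6.12 in replicates 1 to 3 and 6.28 to 6.38 in replicates 4 to 6. For the interactions the real count was 0, which all splits reach, so these 100 of 100 say nothing about chance (highest other 5252 for age, again a structure of the samples, and 4 for CHIR99021). In standard differentiation against stem 2 of 84 splits reached 2806 and in CHIR99021 against stem 2 of 84 reached 4308. In each the other of the 2 was the mirror of the real split within its library set, with 2806 and 4308, and the next gave 551 and 95. The 84 include splits that move stem libraries of the other library set, while each comparison rests on 3 against 3 libraries of 1 set. Such splits are not equal relabellings, so the 2 of 84 do not exclude chance. Among the 8 splits that part the 3 numbered pairs of standard differentiation and stem, the highest besides the real split and its mirror gave 2. With 3 against 3 libraries the 10 splits are too few, with 0 real and 0 at most otherwise under standard differentiation (10 of 10) and between the media (10 of 10), and 2 real and 0 otherwise after CHIR99021 (1 of 10).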

How the results depend on the processing

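The interferon covariate, the libraries left out for Y-linked reads or marker scores and those left out for the differentiation genes were alternatives chosen after seeing the data. Of the 192 refitted values of genes named at E14.5, 122 stayed on their side of the threshold and 70 were weaker, as were 295 and 113 of 408 at E16.5, and 0 changed direction. Of the list calls refitted, 273 of 336 held at E14.5, 225 of 264 at E16.5, 60 of 90 after standard differentiation, 66 of 75 after CHIR99021, 112 of 147 for the interaction with CHIR99021, 392 of 455 over both ages and 82 of 105 over both media. Of the rest, 1 list call each at E16.5, after standard differentiation, for the interaction and over both media changed direction, and the others were weaker. The cause was not tested for any change below, except that leaving out libraries leaves fewer samples.

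The DESeq2 Wald test called 106 genes at E14.5, 1.1e+02 (to 2 digits) at E16.5, 1 for the age interaction, 449 over both ages, 19 after standard differentiation, 44 after CHIR99021, 4 for the interaction with CHIR99021, 144 over both media and 230 between the media. It has no list tests. With no filter on low counts there was 1 call after CHIR99021 and there were 11 over both media. A fit of the groups compared alone gave 1 at E14.5, 1 at E16.5, 0 after CHIR99021, 1 over both media and 1798 for standard differentiation against stem. That fit was not run for the age interaction, where it equals the first analysis, or between the media, where set and medium coincide. The replicate block gave 29 at E14.5, 53 at E16.5, 0 after CHIR99021 and 3 over both media, and between the media it gave 3 when the stem libraries and the set term were dropped with it.

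With a Y-linked covariate E14.5 gave 15 genes. With the junctional zone score E14.5 gave 5 and E16.5 55. With the decidua score these gave 19 and 11, the average over both ages 121, and the decidua list at E16.5 turned to -0.08. With the erythroid score the counts were 3, 20 and 95, and with the interferon score, a list that itself differs by genotype, 1, 1 and 6. Without the library set term standard differentiation against stem gave 4254 and the media 351. Without scrambled standard replicate 3 and KO CHIR99021 replicate 3 together, 3 genes were called after standard differentiation, 0 after CHIR99021 and 11 between the media, and the lipid list of the interaction stood at -0.12. Without the KO libraries that lack Y-linked reads there was 1 call after CHIR99021 and there were 9 over both media, and the sex-linked list turned to 0.23 after standard differentiation and 0.50 over both media. The genes that fall with differentiation, tested after standard differentiation, passed with 200 genes (-0.24, adjusted p = 0.00332), and after CHIR99021 lost the call with an estimated correlation (0.22) and without KO CHIR99021 replicate 3 (0.15), with 0.14 and 0.29 without replicates 1 and 2. Tested after standard differentiation, they also passed without KO replicate 2 (-0.55) or scrambled replicate 1 (-0.32) or 2 (-0.34), and turned to 0.31 without scrambled replicate 3. The rising genes passed there without scrambled replicate 1 (-0.23, direction upward) or 2 (0.32), and turned downward without KO replicate 1 (-0.31) or scrambled replicate 3 (-0.56). All calls of these genes after standard differentiation were lost with an estimated correlation (adjusted p from 0.22 to 0.796).

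Leaving out each library in turn gave 2 (KO replicate 2) to 27 (WT replicate 5) at E14.5, 14 (KO replicate 1) to 54 (KO replicate 4) at E16.5, 0 for the age interaction, 170 to 313 over both ages and 4485 to 5808 for WT age. In mTSC it gave 0 to 1 (scrambled replicate 1 or 2) after standard differentiation, 0 (scrambled replicate 1) to 3 (KO replicate 2) after CHIR99021, 0 to 1 for the interaction and 3 to 11 over both media. For scrambled cells it gave 1349 (replicate 2) to 3501 (replicate 3) for standard differentiation against stem, 2921 (stem replicate 5) to 4441 for CHIR99021 against stem and 0 to 3 (standard replicate 3) between the media. DESeq2 size factors, the transcript length offset and the stricter filter kept every total of genes within 1.5 times, although the higher genes at E14.5 went from 3 to 1 with DESeq2 size factors and those over both media from 2 to 1 with the length offset.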

Other observations

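The KO effect was averaged over both ages of the labyrinth and over both media of mTSC after the data were seen, and the Y-linked reads were looked up after the data were seen. Over both ages edgeR called 252 genes in KO labyrinth, 68 higher and 184 lower (2062 at an unadjusted p under 0.05). In the layer II list, Synb (-0.80 ± 0.13, adjusted p = 0.00169), Gcm1 (-0.63 ± 0.13, adjusted p = 0.0101) and Slc16a3 (-0.56 ± 0.09, adjusted p = 0.00108) fell. Of the 8 genes, 4 fell over all genes and 5 adjusted over the list alone, while Vcan (0.08), Anxa1 (0.14) and Igf1r (-0.08) did not pass (median -0.41, camera adjusted p = 4.32e-07, and 0.0287 with an estimated correlation). The glucose transporter Slc2a3 (-0.49 ± 0.10, adjusted p = 0.0087) and the glutamine transporter Slc1a5 (-0.55 ± 0.09, adjusted p = 0.00183) fell, and 2 of 6 glucose and lactate transport genes passed, 3 adjusted over the list alone (median -0.25, adjusted p = 2.61e-05, and 0.035 with an estimated correlation). Vegfa, the vascular growth factor, fell (-0.34 ± 0.06, adjusted p = 0.00305), as did the endothelial Egfl7 (-0.34 ± 0.07, adjusted p = 0.00725) and the imprinted Mest (-0.40 ± 0.09, adjusted p = 0.0288). Of 14 endothelium genes 1 passed over all genes and 7 adjusted over the list alone (median -0.27, adjusted p = 3.65e-07, and 0.188 with an estimated correlation). Interferon response genes rose, with Irf7 at 0.38 ± 0.07 (adjusted p = 0.00527), Ifit1 at 0.70 ± 0.15 (adjusted p = 0.0116) and Usp18, which restrains interferon signalling, at 0.51 ± 0.10 (adjusted p = 0.0063). Of the 12 on the list 4 passed over all genes and 8 adjusted over the list alone (median 0.33, adjusted p = 1.59e-10, and 0.035 with an estimated correlation). Without 1 library the total ran from 170 to 313. It was 121 with the decidua score as a covariate (117 of the 252 kept), 95 with the erythroid score (93 kept) and 6 with the interferon score (5 kept).

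Over both media, 5 genes were called in KO mTSC (1386 at an unadjusted p under 0.05). Besides Trpv2, the claudin Cldn7 (-4.61 ± 0.54, adjusted p = 0.00177) and F3, tissue factor (-1.05 ± 0.14, adjusted p = 0.00477), fell, while Hand1, which drives giant cell differentiation, rose (1.16 ± 0.19, adjusted p = 0.0369), as did Gm20683 (adjusted p = 0.0321). Cldn7 and Hand1 lie on chromosome 11 with Trpv2, and whether this bears on their change was not tested. The p-values over both media treat the libraries of both media as separate cultures, which the labels do not state. The 10 interferon response genes passed adjusted over the list alone and none over all genes (median -2.49, camera adjusted p = 1.22e-13, and 0.0659 with an estimated correlation). Of 18 cell cycle genes 9 passed adjusted over the list alone and none over all genes (median 0.36, adjusted p = 3.37e-13, and 0.0481 with an estimated correlation). Across genes the KO effects of labyrinth and mTSC had r = -0.03, which rests on genes that are not independent replicates. The count was 3 without KO standard replicate 1 or 2, KO CHIR99021 replicate 1, or scrambled replicate 2 of standard or 1 or 2 of CHIR99021. It was 11 without KO standard replicate 3 and 8 without KO CHIR99021 replicate 2. A fit of the groups compared alone kept 1 of the 5 calls, and the replicate block gave 3 calls and kept 2 of the 5. In both fits neither Hand1 nor Gm20683 passed, and they were also lost without KO standard replicate 1 or 2, KO CHIR99021 replicate 1 or any 1 of the scrambled libraries. Hand1 was lost as well without KO CHIR99021 replicate 3 and with the length offset.

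Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) had 0 reads in KO standard replicate 1 and KO CHIR99021 replicate 2, and 300 reads or more in all other mTSC libraries. In labyrinth, replicates 1 to 3 held 0 to 12 such reads and replicates 4 to 6 held 1329 to 3376, in both genotypes at both ages, except that WT replicate 3 at E16.5 held 1752. Gm20683 stood at 4.44 to 6.29 CPM in KO and 3.94 to 4.55 CPM in scrambled cells after standard differentiation, although it differed after CHIR99021.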
